A study of Mus musculus with 20 samples.

How the data were processed

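The series holds RNA sequencing of mouse tissue, with 8 samples of normal lung, 6 tumours induced with a vector of luciferase, Mycl and hairpins against p53 and Rb, and 6 tumours of the same vector with IkBaM in place of luciferase. Per the labels' protocols, tumours were taken from mice at a clinical endpoint, normal tissue was dissected off them under a microscope, RNA was purified with a column kit that includes a DNase step, and libraries were made with a TruSeq RNA kit. Per the submitters' processing notes, STAR 2.3.0e, Cuffdiff 2.1.1 and the mouse genome build mm9 were used. Whether fragments were counted by strand, and which annotation was used, is not given in the sources used here.

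The deposited table lists, for each of 30967 RefSeq transcript records and 20 libraries, 2 kinds of value that the authors made with Cuffdiff: an estimated count of fragments before scaling between libraries, and FPKM (fragments scaled to transcript length and library size), which the authors' tool scaled between libraries. The estimated counts deposited are expected counts, since Cuffdiff shares fragments between overlapping records, and 29.5% of them were not whole. Libraries are named by condition (q1, q2, q3) and a replicate number, with no sample title. Condition q1 was read as normal lung by its 8 libraries, the number that normal lung alone has. Conditions q2 and q3 have 6 libraries each, as both tumour groups do, so their vectors were left open and they are named q2 tumours and q3 tumours. No sample's condition was read from its values.

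Records were joined to symbols through a RefSeq gene table of the GRCm38 assembly (30474 records) and the GENCODE M21 metadata (178 records). The 315 records without a symbol were kept under their own identifier. Since the reference differs from the build of the files, no coordinate is given. Estimated counts were summed over the records of a gene (4244 genes had more than 1), which gave 23523 genes, and 98.5% of the sums were within 0.01 of a whole number. Sums were rounded to whole numbers. The table marks some records as failed or as too deep to quantify, and gives those a 0 in a whole condition (1 such deep record in q1, 20 in q2 and 28 in q3), so 33 genes with such a record were left out, among them Cd44, Stat3 and Malat1. Totals per library were 777649 to 15918423 fragments.

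Every pair of libraries of a condition was compared by a chi-square over genes with at least 10 fragments in the pair. Pairs below 2 per gene were counted as 1 sample and their fragments added, and their FPKM averaged. This gave 9 pairs among the 58, and 11 samples of 2306473 to 21719193 fragments. The design written before the data were examined had all 20 libraries as separate samples. It was replaced for this reason, and the fit with all 20 is kept as an alternative. The chi-square was tested on simulated libraries beforehand.

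Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr on the groups, TMM factors, glmQLFit and glmQLFTest) in a single fit of 11 samples with group as the only factor, which left 8 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 15727 genes tested. CPM (counts scaled to library size) use the TMM-scaled library sizes. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. A total of 30 gene lists, fixed before the data were examined, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with the correlation between members estimated, and the lists of engineered and of sex-linked genes were described gene by gene. Beside each list stands the number of members that pass when p-values are adjusted over the list alone. Fry tests whether the members of a list move one way on balance, and compares the list with no other genes.

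Genes were named by a rule fixed beforehand. For each tumour group against normal lung it takes the 4 engineered genes, the 5 largest rises and 5 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between samples, and from each list the 2 called members with the largest change and a mean of at least 1 CPM. Because it is not known which tumour group carries luciferase, the part written for that group was applied to both. Between the tumour groups, where no gene was called, it takes the 5 genes each way with the smallest unadjusted p, and 2 members of each of 10 lists. Predicted genes, pseudogenes and receptor segments are counted and not named, and a few genes that the rule took are not reported here.

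Counts were simulated with each gene's mean over all samples and the dispersions and sizes of these samples. In them 100 genes changed 2-fold and 100 changed 4-fold, drawn from the better covered genes. EdgeR called 2 and 42 of them for q2 tumours against normal lung (15353 genes in the step) and 5 and 61 for q3 tumours against normal lung (15343 genes). For q3 against q2 tumours (15343 genes) it called 3 and 40, and the unchanged genes called were 4, 2 and 2. In the same kind of data for q2 tumours against normal lung (15727 genes), DESeq2 called 95 of the 200 changed and 38 unchanged genes, and limma-voom 53 and 6. Since only 200 genes changed, the adjustment was stricter than in the real comparisons with normal lung, and these shares do not carry over to them. Camera called a list of 48 members shifted 4-fold in each comparison, and no other list, where genes were drawn without correlation. The depth of 2306473 fragments in the shallowest sample limits what can be said of genes at a few CPM.

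Alternatives planned beforehand were RLE factors, library size alone, the Wald test of DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), no filter beyond 1 fragment, a filter of 1 CPM in 6 libraries, a fit of the compared groups alone, 1 surrogate variable from sva 3.50.0, a sex covariate (the summed level of 4 Y-linked genes), a 2-fold or an adjusted p under 0.01 as added threshold, leaving out each sample, and for the lists the preset correlation and fry. The fit of 20 libraries counted separately was the design written beforehand, and became an alternative after the pairs were seen. Chosen after seeing the data were the deeper library of each pair and leaving out 90 genes whose counts differed between libraries of a sample (chi-square over 30). Leaving out normal lung samples 2 and 4, and q2 tumour 2 with q3 tumour 1, was also chosen then. So was leaving out each sample for the q3 tumours against normal lung and for the lists. Scripts ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.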

Results

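RNA sequencing was used to compare normal mouse lung with small cell lung cancers (SCLC), a neuroendocrine lung tumour, that had been induced with lentiviral vectors. Each vector carried Mycl, a proto-oncogene of the MYC family, with short hairpin RNAs against p53 and Rb. The remaining insert was either luciferase, a reporter enzyme, or IkBaM, a mutant of IkBa, the inhibitor that holds NF-kB in the cytoplasm. The labels describe 8 samples of normal lung, 6 tumours of the luciferase vector and 6 tumours of the IkBaM vector. The title of 1 IkBaM tumour begins with WT, as titles of luciferase tumours do, and its group was taken from its source name and genotype. The deposited values name their libraries only by a condition and a replicate number, with 8 libraries in condition q1, 6 in q2 and 6 in q3. Condition q1 was taken as normal lung because normal lung is the only group of 8. Which of q2 and q3 held the luciferase tumours and which the IkBaM tumours is not known here, so both are named q2 tumours and q3 tumours throughout. No difference between them is assigned to a vector. The libraries held between 777649 and 15918423 fragments on genes.

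Before any averaging, the libraries of each condition were compared pair by pair. In 9 of the 58 pairs the fragment counts agreed nearly within sampling noise, with a chi-square per gene of 1.18 to 1.58, and in the other 49 pairs it was 3.33 to 85.39. Over well covered genes the SD of the log2 ratio between the libraries of such a pair was 0.95 to 1.1 times the SD that counting gives, and at least 2.13 times that SD in every other pair. The libraries of these 9 pairs were counted as 1 sample each and their fragments were added. This left 11 samples, 4 of normal lung, 3 of q2 tumours and 4 of q3 tumours, with 2306473 to 21719193 fragments each. No label says that the samples came from separate animals, so p-values measure the spread between these samples only.

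**Figure D1:**
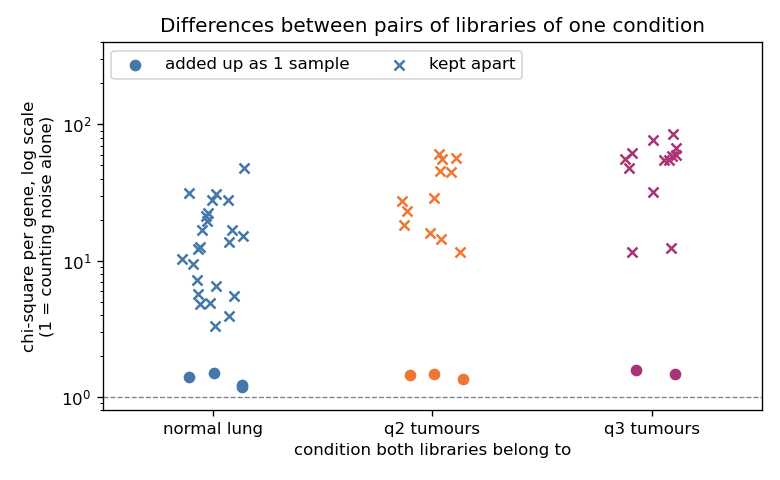
Chi-square per gene between every pair of libraries of a condition, on a log axis, where 1 is counting noise alone. Circles are the 9 pairs added up as 1 sample (1.18 to 1.58) and crosses the pairs kept apart (3.33 or more).

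Gene levels are given as CPM, fragment counts scaled to library size. The first principal component of log2 CPM took up 59.2% of the variance and separated normal lung, at -161.6 to -114, from every tumour, at 19.1 to 103.3. The second took up 11.1% and spread the q3 tumours from -40.3 to 105.9, with q2 tumours between -67.2 and -7. Correlations across genes were 0.925 to 0.957 between normal lung samples, 0.863 to 0.915 between q2 tumours, 0.87 to 0.951 between q3 tumours and 0.858 to 0.936 between tumours of different groups. The range between tumours of different groups thus overlapped the range within each tumour group.

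**Figure D2:**
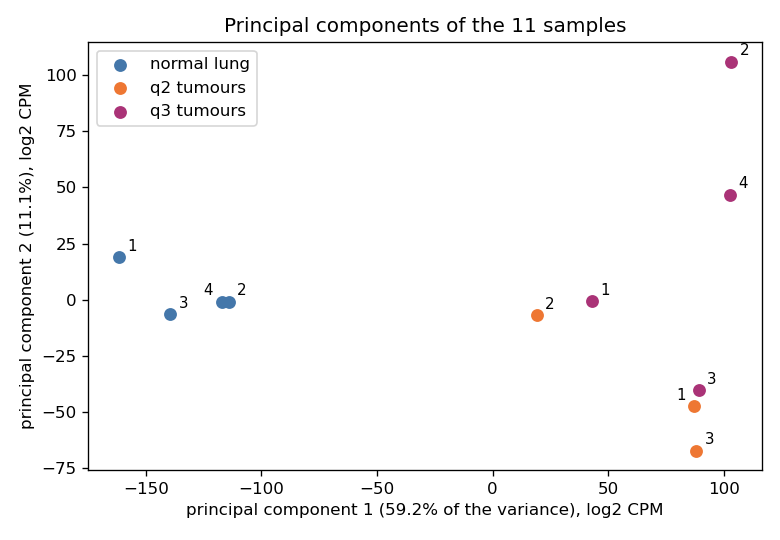
First and second principal components of log2 CPM for the 11 samples, numbered within their group. The 4 normal lung samples lie at the left (first component -161.6 to -114) and the 7 tumours at the right (19.1 to 103.3), with q2 and q3 tumours intermingled.

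The genes that the vectors carry or target were examined first. CPM are given as mean ± SD over 4 normal lung samples, 3 q2 tumours and 4 q3 tumours, and log2 fold changes as value ± SE. Adjusted p comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 15727 genes. Mycl was at 20.8 ± 4.72 CPM in normal lung (SD, n = 4), 80.1 ± 22.7 in q2 tumours (n = 3) and 69.1 ± 51 in q3 tumours (n = 4). It rose in q2 tumours (1.94 ± 0.44, adjusted p = 0.0053) and in q3 tumours (1.74 ± 0.42, adjusted p = 0.0055). The q3 tumours ranged from 38.9 to 145 CPM, with the highest value in sample 1, and without that sample the log2 fold change was 1.07 and still passed. Rb1, the retinoblastoma gene, fell from 151 ± 14.4 CPM in normal lung to 39.6 ± 13.2 in q2 tumours (-1.94 ± 0.27, adjusted p = 4.7e-04) and 57.7 ± 11.8 in q3 tumours (-1.39 ± 0.24, adjusted p = 8.1e-04). Trp53, which encodes p53, fell from 18.9 ± 5.56 CPM to 8.42 ± 2.12 (-1.17 ± 0.36, adjusted p = 0.024) and 8.1 ± 2.35 (-1.21 ± 0.33, adjusted p = 0.010). Its call in q2 tumours was lost without normal lung sample 3 (-0.95, adjusted p = 0.082), without normal lung sample 4 (-1.08, adjusted p = 0.061) and without q2 tumour 1 (-0.96, adjusted p = 0.094). With a sex covariate Mycl in q3 tumours (1.82, adjusted p = 0.057) and Trp53 in q2 tumours (-1.02, adjusted p = 0.099) and q3 tumours (-1.0, adjusted p = 0.12) no longer passed. All q3 tumours were female, so in that comparison the covariate partly follows the group, and lost calls alone do not show an effect of sex. All 3 changes were in the direction that the vectors' design gives. Tumour pieces were compared with whole lung, and no tumour lacked the hairpins or Mycl. Direction alone therefore does not show an effect of the vectors on these genes. Nfkbia, which encodes IkBa, fell from 156 ± 31.1 CPM to 76.2 ± 20.4 in q2 tumours (-1.03 ± 0.24, adjusted p = 0.0057) and 80.7 ± 9.33 in q3 tumours (-0.95 ± 0.22, adjusted p = 0.0039). None of the 4 genes differed between q3 and q2 tumours by this test, where Nfkbia gave 0.08 ± 0.23 (adjusted p = 0.93), so Nfkbia did not separate the tumour groups. Fragments of a vector's coding sequence can add to Mycl and Nfkbia where they align, and none of the sources used here says whether they do.

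**Figure D3:**
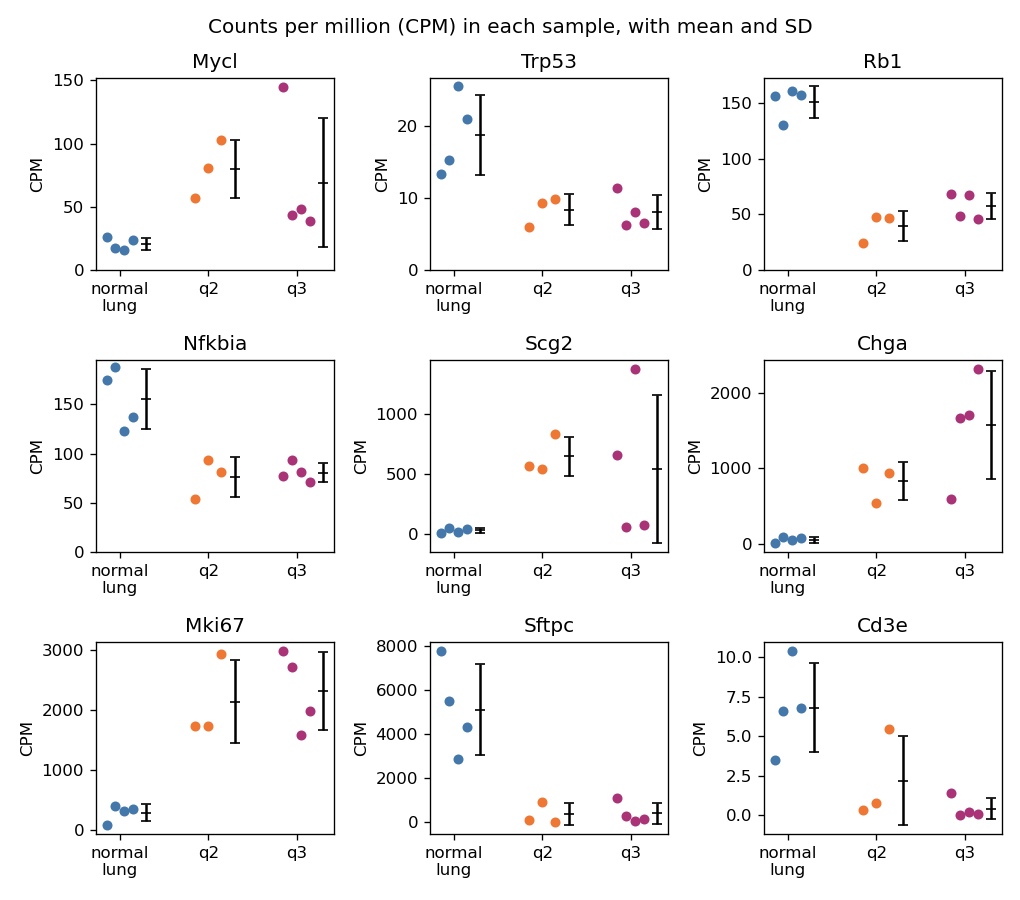
CPM of 9 genes in every sample (points), with mean and SD beside them, for 4 normal lung samples, 3 q2 tumours and 4 q3 tumours. Rb1 is at 130 to 161 CPM in normal lung and at 24.3 to 68.5 CPM in the tumours, and Chga is at 3.22 to 91 CPM in normal lung and 539 to 2310 CPM in the tumours.

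The comparison of q2 tumours with normal lung asks which genes differ between SCLC and the tissue it arises in. Most listed neuroendocrine and proliferation genes were higher in the tumours, and most listed genes of alveolar epithelium, blood vessels and smooth muscle were lower. These are counts of single genes: with an estimated correlation between members camera called none of the lists (adjusted p = 0.34 for the neuroendocrine, E2F, alveolar type 1, endothelial and smooth muscle lists and 0.38 for alveolar type 2). Of 15727 genes tested, 5781 (36.8%) passed, 2754 higher and 3027 lower, and 4838 of these changed at least 2-fold. Scaled by library size alone, 4075 were higher and 2394 lower. The counts of called list members below are to be read against that 36.8%. Among others, the NF-kB pathway, p53 target, CREB pathway, BCL2 family and interferon response lists did not exceed it. Of 28 tested neuroendocrine genes, 25 rose, 1 fell and 2 did not pass (26 adjusted over the list alone), with a median log2 fold change of 3.77. Scg5, which encodes a secretory granule protein, rose from 7.29 ± 5.84 to 179 ± 48.8 CPM (4.73 ± 0.67, adjusted p = 4.8e-04), and Scg2, which encodes a granin, from 26.3 ± 22.1 to 649 ± 162 CPM (4.66 ± 1.15, adjusted p = 0.0083). These transcripts were not absent from normal lung: Scg2 stood at 2.52, 48.6, 12.9 and 41.3 CPM in normal lung samples 1, 2, 3 and 4. Among 13 genes used to define SCLC subtypes, 6 rose and 3 fell (10 passed adjusted over the list alone). Yap1, a Hippo pathway coactivator, was among those that fell, from 163 ± 39.8 to 14.7 ± 12.2 CPM (-3.48 ± 0.51, adjusted p = 5.5e-04).

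Of 48 E2F target and mitotic genes, 47 rose and none fell, with a median log2 fold change of 2.55 (48 passed adjusted over the list alone). Cdk1, the mitotic kinase, rose from 17 ± 7.9 to 188 ± 50.2 CPM (3.48 ± 0.46, adjusted p = 3.9e-04) and its partner Ccnb1 from 2.62 ± 2 to 34.2 ± 6.84 CPM (3.66 ± 0.57, adjusted p = 7.2e-04). The p53 target list showed no common direction, since 6 of 25 members rose, 2 fell and 17 did not pass (8 adjusted over the list alone). Fas, a death receptor, fell (-4.21 ± 0.53, adjusted p = 3.5e-04), and Gtse1, a protein of dividing cells that restrains p53, rose (2.97 ± 0.38, adjusted p = 3.6e-04). Of 33 NF-kB target genes, 19 fell and none rose (20 adjusted over the list alone), and of 23 genes of the NF-kB pathway itself 7 fell and 1 rose (7 adjusted over the list alone). Levels are those of whole tissue pieces, where 17 of 18 endothelial and 11 of 18 macrophage genes fell too. Falls in the pathway lists are therefore not assigned to tumour cells. Icam1, an adhesion molecule, fell from 503 ± 80.5 to 43.2 ± 33.8 CPM (-3.54 ± 0.59, adjusted p = 0.0010). Ccl20, a chemokine, was at 3.04 ± 4.09 against 0.149 ± 0.207 CPM (-4.41 ± 1.6, adjusted p = 0.049). Irak4, a kinase of Toll-like receptor signalling, fell (-1.87 ± 0.33, adjusted p = 0.0013), as did the subunit gene Nfkb2 (-1.42 ± 0.44, adjusted p = 0.025). Of 16 Notch genes 9 fell and 2 rose (13 adjusted over the list alone). Notch1 fell (-3.37 ± 0.45, adjusted p = 4.1e-04), and Dll3, an inhibitory ligand, rose from 2.03 ± 1.28 to 25.1 ± 6.73 CPM (3.78 ± 0.49, adjusted p = 3.6e-04). Of 20 hypoxia and glycolysis genes 12 rose and 1 fell (17 adjusted over the list alone), including Egln3 (4.22 ± 0.73) and the aldolase gene Aldoc (2.94 ± 0.35). The CREB pathway went both ways, with 4 of 30 members higher and 5 lower (8 adjusted over the list alone): the adenylyl cyclase gene Adcy1 rose (3.38 ± 0.65) and the phosphodiesterase gene Pde4b fell (-3.97 ± 0.61). The BCL2 family did so too, with 2 of 16 higher and 2 lower (4 adjusted over the list alone), a median of -0.05 and a mean of 0.01, which differ in sign. Bok rose (1.84 ± 0.55), while Mcl1, a survival factor, fell (-1.57 ± 0.27).

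All 14 alveolar type 1 genes fell (14 adjusted over the list alone), including Cav1, the caveolin of thin epithelium and endothelium (1720 ± 390 to 84 ± 85.8 CPM, -4.36 ± 0.8), and Hopx (-4.34 ± 0.65). Of 14 alveolar type 2 genes 11 fell (14 adjusted over the list alone). Among them were Sfta2 (-4.47 ± 1.21) and the phosphate transporter gene Slc34a2 (-4.11 ± 1.49). Alveolar genes stood at a median of 17.1% of their normal lung level in q2 tumour 2, against 2.66% and 2.13% in q2 tumours 1 and 3, and without q2 tumour 2 Slc34a2 was at -7.63 and Sfta2 at -7.01. Of 11 club cell genes 4 fell (5 adjusted over the list alone), among them Cyp2b10 (-4.68 ± 1.36) and Cckar (-3.61 ± 1.23). Of 13 ciliated cell genes 4 fell and 1 rose (6 adjusted over the list alone), with falls in Tekt1 (-2.98 ± 0.94) and Tppp3 (-2.52 ± 0.56). Of 18 endothelial genes 17 fell (18 adjusted over the list alone), such as Calcrl, a receptor of adrenomedullin (3220 ± 1090 to 107 ± 135 CPM, -4.91 ± 0.95), and the capillary carbonic anhydrase gene Car4 (-4.78 ± 0.76). In the stroma 8 of 16 fibroblast genes fell (8 adjusted over the list alone), including Tcf21 (-5.48 ± 1.11) and Inmt (-4.91 ± 1.38). So did 11 of 12 smooth muscle genes (12 adjusted over the list alone), including Hhip (-3.76 ± 1.04) and Higd1b (-3.62 ± 0.53). Of 18 macrophage genes 11 fell (12 adjusted over the list alone), with Chil3 at -4.82 ± 1.18 and Siglecf, a lectin of alveolar macrophages, at -4.67 ± 1. Falls were also called in 7 of 11 neutrophil genes (8 adjusted over the list alone), with Retnlg at -5.31 ± 1.43 and S100a9 at -5.01 ± 1.11. They were called in 6 of 7 erythroid genes (6 adjusted over the list alone), with Hba-a1 at -4.45 ± 0.64 and Alas2 at -4.35 ± 0.65. Of 9 natural killer cell genes 6 fell (6 adjusted over the list alone), with Ncr1 at -4.28 ± 0.98 and Nkg7 at -2.73 ± 0.65. Of 10 class II antigen presentation genes 7 fell (7 adjusted over the list alone), with H2-DMb1 at -2.76 ± 0.44 and the transactivator gene Ciita at -2.53 ± 0.66. In class I, 6 of 14 fell (7 adjusted over the list alone), with Psmb10 at -2.27 ± 0.51 and H2-T23 at -1.49 ± 0.38. Of 22 interferon response genes 5 fell and 1 rose (6 adjusted over the list alone), with Gbp2 at -3.39 ± 0.54 and Ifit3 at -3.16 ± 0.59. Of 15 immediate early and stress genes 7 fell (8 adjusted over the list alone), with Ier3 at -3.29 ± 0.51 and Hspa1a at -2.69 ± 0.9. Of 6 liver genes 2 fell (2 adjusted over the list alone), Fga at -5.06 ± 1.56 and Apob at -4.88 ± 1.68. Both were high only in normal lung samples 2 and 4, with Fga at 24.3 and 15.5 CPM against 0.697 and 1.86 in samples 1 and 3. Apob was at 10.4 and 9.68 CPM against 1.02 and 2.81. Without normal lung sample 2 Fga was at -4.19. Few members passed in the T cell list (1 of 15, Cd3g at -2.33 ± 0.76), the B and plasma cell list (1 of 14, Cd22 at -2.12 ± 0.72), the cardiac and skeletal muscle list (1 of 14, Myh7 at -2.29 ± 0.74) and the adipocyte list (1 of 9, Pparg at -1.85 ± 0.34). Adjusted over the list alone, these 4 lists had 0, 0, 0 and 1 members. T and B cell genes stood at a median of 7.54%, 21.9% and 72.9% of their normal lung level in q2 tumours 1, 2 and 3. Without q2 tumour 3 Cd3g was at -3.21 and Cd22 at -2.72. The adipocyte list as a whole lay the other way from Pparg, with a median of 1.8 and a mean of 1.01 (camera adjusted p = 0.96 with an estimated correlation). That direction rests on q2 tumours 2 and 3, where adipocyte genes stood at a median of 458% and 408% of their normal lung level. In q2 tumour 1 the median was 0%.

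By the rule for single genes, the largest rises without overlap between samples were in 5 genes. They were Eif4g1, Ceacam10 (6.24 ± 1.48), Iapp (5.51 ± 1.52), which encodes the islet hormone amylin, Cbln4 (5.25 ± 0.87) and the tight junction gene Cldn9 (5.14 ± 0.83). The rises of 3 of them leaned on q2 tumour 2. Without it the log2 fold change was 1.82 for Iapp (adjusted p = 0.26), which then did not pass, 4.07 for Ceacam10 and 4.11 for Cbln4. Eif4g1, a translation factor that every cell uses, is listed with at most 2 fragments in any normal lung library, and with 0 fragments in 1 library of q2 tumour 3 against 1545 in the other. The records without a symbol were searched for the one that, added to Eif4g1, best evened out the libraries of a sample. With it the highest chi-square between such libraries was 5.07 in place of 216. The summed level was 499 ± 82.2 CPM in normal lung, 496 ± 27.7 in q2 tumours and 527 ± 70.2 in q3 tumours. That this record is a transcript of Eif4g1 is not shown. Given the uneven libraries, the listed rise of Eif4g1 is not taken as a change in expression. The largest falls were in Vsnl1, a neuronal calcium sensor gene (11.5 ± 3.11 to 0.0858 ± 0.149 CPM, 2 fragments in all over the q2 tumours), Mroh2a (12.1 ± 12.8 to 0.115 ± 0.109 CPM, 3 fragments in all), the noradrenaline transporter gene Slc6a2 (230 ± 121 to 2.4 ± 3.62 CPM, -6.68 ± 1.21), Tcf23 (-5.77 ± 1.17) and Tmem100, an endothelial gene (619 ± 219 to 11.7 ± 18.6 CPM, -5.76 ± 1.37). Mroh2a stood at 1.61, 19.3, 0.832 and 26.5 CPM in normal lung samples 1 to 4, so its mean there rests on samples 2 and 4. Without q2 tumour 2 the log2 fold change was -9.23 for Slc6a2, -9.4 for Tmem100, -10.06 for Tcf23 and -9.92 for Vsnl1. Tcf23 and Vsnl1 were at 0 CPM in q2 tumours 1 and 3. With the correlation between members estimated, camera called none of the 30 lists, with adjusted p from 0.34 to 0.96, while it called 21 with a preset correlation of 0.01 and fry called 22. Leaving out single samples ended the calls of 19 of the 70 genes that the rule took, with adjusted p between 0.051 and 0.26: Apob, Bok, Cckar, Ccl20, Cd22, Cd3g, Cyp2b10, Fga, Hhip, Hspa1a, Iapp, Inmt, Myh7, Nfkb2, Retnlg, Sfta2, Slc34a2, Tekt1 and Trp53. The sex covariate ended 11 calls: Ccl20, Cd22, Cd3g, Ciita, H2-T23, Hspa1a, Myh7, Nfkb2, Slc34a2, Tekt1 and Trp53. The fold of 32 of the 70 moved by over 1.5 times without q2 tumour 2, of 7 without q2 tumour 1 and of 6 without q2 tumour 3. It did so for 5, 4 and 2 genes without normal lung samples 2, 3 and 4. Without q2 tumour 2 Calcrl was at -6.79, Inmt at -7.69, Cyp2b10 at -7.87 and Cckar at -7.18. Hspa1a was at -1.37 without normal lung sample 3, and Bok at 1.2 without q2 tumour 1. The number of calls lost was 17 without q2 tumour 1, 10 without q2 tumour 3 and 5 without q2 tumour 2. It was 4, 3, 8 and 7 without normal lung samples 1, 2, 3 and 4.

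**Figure D4:**
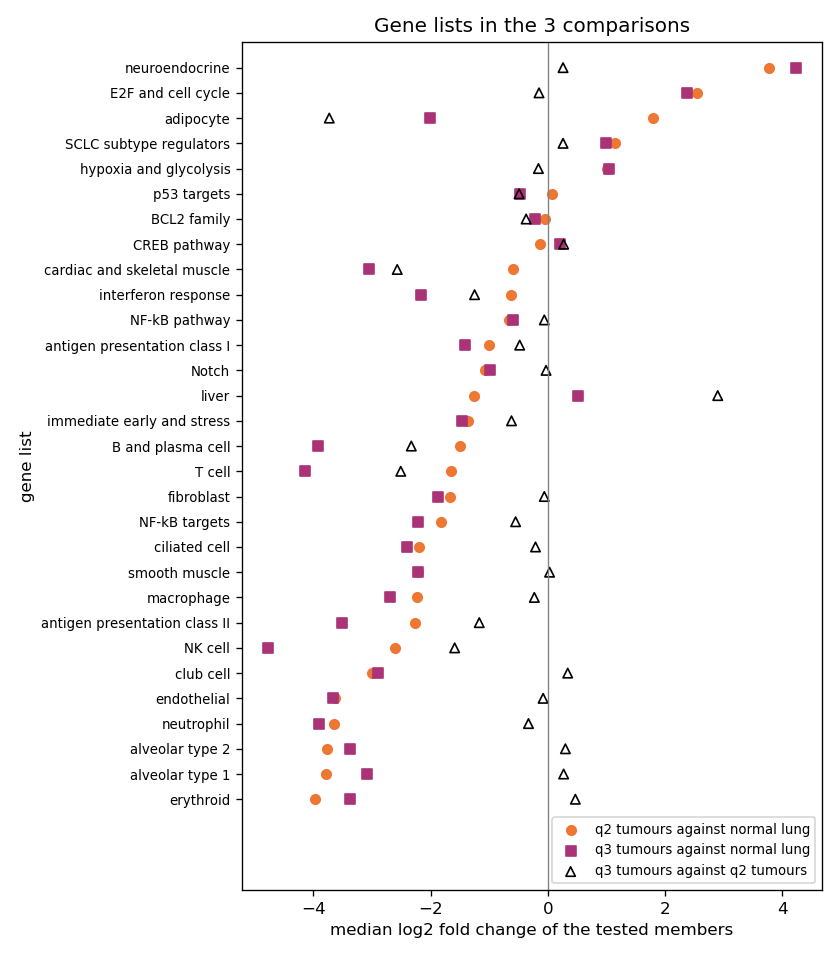
Median log2 fold change of the tested members of each of 30 gene lists in the 3 comparisons. Neuroendocrine genes lie at 3.77 and 4.23 in q2 and q3 tumours against normal lung, and T cell genes at -1.65 and -4.15.

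The same question was put to q3 tumours against normal lung, where 7389 genes (47%) passed, 3496 higher and 3893 lower, and 5927 changed at least 2-fold. Scaled by library size alone, 4115 were higher and 3443 lower. Among others, the p53 target, CREB pathway, BCL2 family and cardiac and skeletal muscle lists did not exceed the 47% called over all genes. Of 28 neuroendocrine genes 24 rose and 2 fell (28 passed adjusted over the list alone), with a median of 4.23. Chgb, a granin gene, rose from 30.8 ± 29.5 to 1110 ± 904 CPM (5.21 ± 1, adjusted p = 0.0015). Of 13 subtype regulators 6 rose and 3 fell (11 adjusted over the list alone). Neurod1, a neuronal transcription factor, was at 3.48 ± 3.41 CPM in normal lung and 76.6 ± 81.7 in q3 tumours (4.69 ± 1.52, adjusted p = 0.025), with values of 14.5, 165, 0.121 and 127 CPM in q3 tumours 1, 2, 3 and 4. Of 48 E2F target and mitotic genes 46 rose and none fell (47 adjusted over the list alone), with Ccne2 at 22.6 ± 11.5 against 246 ± 100 CPM (3.46 ± 0.48) and E2f8 at 3.44 ± 0.54. In the p53 target list 5 of 25 rose and 6 fell (11 adjusted over the list alone), with Fas at -3.82 ± 0.47 and Gtse1 at 2.42 ± 0.36. Of 33 NF-kB targets 26 fell and none rose (28 adjusted over the list alone), with Il1b, an inflammatory cytokine gene, at 35.1 ± 20.2 against 0.77 ± 0.797 CPM (-5.35 ± 0.83, adjusted p = 4.3e-04). The chemokine gene Ccl5 was at -4.45 ± 0.86. As in q2 tumours, falls in the pathway lists are not assigned to tumour cells. Of 23 NF-kB pathway genes 10 fell and 2 rose (14 adjusted over the list alone), with the subunit genes Rel (-2.52 ± 0.46) and Nfkb2 (-1.97 ± 0.41) among the falls. In the CREB pathway 8 of 30 rose and 6 fell (14 adjusted over the list alone), with Vgf, which encodes a neuropeptide precursor, at 4.33 ± 0.97 and Pde4b at -3.87 ± 0.54. Of 16 Notch genes 9 fell and 2 rose (11 adjusted over the list alone), with Notch1 at -3.4 ± 0.4 and Dll3 at 3.69 ± 0.47. Of 16 BCL2 family genes 5 fell and 1 rose (6 adjusted over the list alone), with Bcl2 at -1.87 ± 0.35 and Mcl1 at -1.29 ± 0.24. Of 20 hypoxia and glycolysis genes 13 rose and 2 fell (15 adjusted over the list alone), with Egln3 at 4.02 ± 0.71 and Aldoc at 2.57 ± 0.34.

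Most listed lymphocyte genes fell in q3 tumours. With an estimated correlation camera did not call the T cell, B and plasma cell or natural killer cell list (adjusted p = 0.33 for each). Of 15 T cell genes 14 fell (14 adjusted over the list alone), with Cd8a, the co-receptor of cytotoxic T cells, at 10.6 ± 5.54 against 0.0985 ± 0.0761 CPM (-6.29 ± 0.89, adjusted p = 2.6e-04). Cd3d was at 4.44 ± 2.92 against 0.0592 ± 0.0831 CPM, which is 3 fragments over the 4 tumours. Of 14 B and plasma cell genes 12 fell (13 adjusted over the list alone), with Blk at -6.22 ± 1.31 and Cr2 at -6.07 ± 1.46. All 9 natural killer cell genes fell (9 adjusted over the list alone), with Nkg7 at -5.81 ± 0.73 and the perforin gene Prf1 at -5.37 ± 0.88. All 10 class II genes fell (10 adjusted over the list alone), with H2-Ob at -5.06 ± 1.06 and Ciita at -4.39 ± 0.66. So did 12 of 14 class I genes (12 adjusted over the list alone), with H2-Q7 at -3.57 ± 0.46 and Nlrc5 at -3.15 ± 0.47. Of 22 interferon response genes 15 fell and none rose (16 adjusted over the list alone), with Bst2 at -4.25 ± 0.57 and Gbp2 at -4.06 ± 0.5. Of 18 macrophage genes 13 fell (13 adjusted over the list alone), with Siglecf at -4.55 ± 0.89 and Ear2 at -3.61 ± 1.14. In the neutrophil list 7 of 11 fell (8 adjusted over the list alone), with S100a9 at -5.69 ± 1.04 and Cxcr2 at -4.93 ± 0.83. In the erythroid list 6 of 7 fell (6 adjusted over the list alone), with Hbb-b2 at -3.57 ± 0.54.

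Single genes of lung tissue also fell in q3 tumours, though with an estimated correlation camera called none of their lists (adjusted p = 0.33 for both alveolar lists, 0.55 for club and 0.54 for ciliated cells). Alveolar type 1 genes fell in 12 of 14 members (13 adjusted over the list alone), with Cav1 at -4.41 ± 0.71 and Igfbp6 at -4.24 ± 0.83. Alveolar type 2 genes fell in 13 of 14 (13 adjusted over the list alone), with the surfactant protein gene Sftpa1 at 2930 ± 660 against 132 ± 169 CPM (-4.47 ± 1.37) and Cxcl15 at -3.89 ± 1.33. Alveolar genes stood at a median of 20.2% of their normal lung level in q3 tumour 1, against 5.08% to 9.88% in the other q3 tumours, and without q3 tumour 1 Sftpa1 was at -5.94. Of 11 club cell genes 6 fell (7 adjusted over the list alone), with Cyp2f2 at -5.02 ± 1.52 and Cbr2 at -4.07 ± 1.36. Of 13 ciliated cell genes 7 fell and 1 rose (9 adjusted over the list alone), with Ccdc153 at -3.95 ± 1.3 and Sntn at -3.65 ± 1.27. Endothelial genes fell in 17 of 18 members (17 adjusted over the list alone), with Car4 at -6.14 ± 0.73 and Calcrl at -4.95 ± 0.84. Fibroblast genes fell in 13 of 16 (13 adjusted over the list alone), with Tcf21 at -5.05 ± 0.96 and Inmt at -4.37 ± 1.19. Smooth muscle genes fell in 12 of 12 (12 adjusted over the list alone), with Hhip at -3.78 ± 0.94 and Myh11 at -3.49 ± 0.59. Of 14 cardiac and skeletal muscle genes 5 fell (5 adjusted over the list alone), with Ckm at -5.16 ± 1.72 and Myl4 at -3.82 ± 1.37. Both genes were highest in normal lung sample 1, with Myl4 at 124 CPM against 3.07 to 34.7 in normal lung samples 2 to 4, and without that sample Ckm was at -3.39 and Myl4 at -2.32. Of 9 adipocyte genes 4 fell (4 adjusted over the list alone), with Cidec at -5.71 ± 1.41 and Plin4 at -2.5 ± 0.8. Within the q3 tumours Cidec was at 1.24 CPM in sample 1 and at 0.0605 CPM or less in the others, so the size of its fold rests on sample 1. Adipocyte genes stood at a median of 65% of their normal lung level in that sample and at 0% to 6.79% in the other q3 tumours. In the liver list 2 of 6 rose and 1 fell (3 adjusted over the list alone): Ttr, the transthyretin gene, was at 3.4 ± 3.83 against 113 ± 103 CPM (5.39 ± 1.4) and Ahsg at 1.42 ± 1.21 against 24.9 ± 28.9 CPM (4.27 ± 1.31). Of 15 immediate early and stress genes 12 fell and 1 rose (13 adjusted over the list alone), with Hspa1a at -5.24 ± 0.95 and Hspa1b at -4.89 ± 1.06.

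By the rule for single genes, large rises were in Eif4g1, with the limit given above, Nptx2, a neuronal pentraxin gene (6.26 ± 1.2), Tcfl5 (5.62 ± 1.08) and Rgs7, a regulator of G protein signalling (5.49 ± 0.46). Nptx2 stood at 18.9, 343, 35.9 and 325 CPM in q3 tumours 1 to 4, so the size of its rise leaned on samples 2 and 4. The largest falls were in Kdm5d, Ces1g (-7.49 ± 1.64), the lysozyme gene Lyz1 (148 ± 119 to 1.06 ± 0.897 CPM, -7.45 ± 1.1), Wnt2 (22.2 ± 6.76 to 0.107 ± 0.127 CPM, -7.31 ± 0.79) and the fatty acid binding protein gene Fabp1 (-6.9 ± 1.38). Kdm5d lies on the Y chromosome: it was at 28.3 ± 21.5 CPM in normal lung and at 0.0372 ± 0.0444 in q3 tumours, which is 2 fragments in all. By Xist and Y-linked genes, 2 normal lung samples were male, 1 female and 1 held both kinds of transcript, 1 q2 tumour was male and 2 were female, and all 4 q3 tumours were female. Sex was therefore not balanced in this comparison, and with a sex covariate 3925 genes passed. The covariate was at 0.98, 0.001, 1 and 0.496 of its highest value in normal lung samples 1 to 4 and at 0.002 or less in q3 tumours. It thus partly follows the group, which by itself can end calls. Mycl was at 1.82 in place of 1.74 and Trp53 at -1.0 in place of -1.21, so lost calls alone do not show an effect of sex. With an estimated correlation camera called none of the 30 lists here (adjusted p from 0.29 to 0.87), against 23 with the preset correlation and 26 by fry. Leaving out single samples ended the calls of 11 of the 72 genes that the rule took, with adjusted p between 0.051 and 0.16: Ahsg, Cbr2, Ccdc153, Ckm, Cxcl15, Ear2, Myl4, Neurod1, Plin4, Sftpa1 and Sntn. The sex covariate ended 21 calls: Ahsg, Cbr2, Ccdc153, Ckm, Cxcl15, Cyp2f2, Ear2, Hhip, Hspa1b, Inmt, Kdm5d, Mycl, Myl4, Neurod1, Nfkb2, Plin4, Sftpa1, Sntn, Trp53, Ttr and Vgf. The fold of 28 of the 72 moved by over 1.5 times without q3 tumour 1, and of 1, 1 and 4 without q3 tumours 2, 3 and 4. It did so for 6, 5, 6 and 4 genes without normal lung samples 1 to 4. Without normal lung sample 3 Hspa1b was at -3.16 and Hspa1a at -3.9, and without q3 tumour 4 Ahsg was at 3.31. All 11 calls were lost without q3 tumour 4, 8 without q3 tumour 2 and 6 without q3 tumour 3. The number was 9, 4 and 2 without normal lung samples 1, 2 and 3. Genes with near-identical copies, among them Hba-a1, Hbb-b2, Hspa1a, Hspa1b, H2-Q7 and Akr1c12, are uncertain where fragments could be split between copies.

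The direct comparison of q3 with q2 tumours asks whether tumours of the 2 vectors differ. No gene passed edgeR's test, with 1600 of 15727 genes at an unadjusted p under 0.05. DESeq2 called 113 genes, limma-voom 0, limma on log2(FPKM + 1) 0 and limma on log2(FPKM + 0.1) 2. In the simulated data for q2 tumours against normal lung, DESeq2 called 38 unchanged genes beside 95 changed ones. Part of its 113 calls may therefore be false. Leaving out q2 tumour 2 gave 7 genes, leaving out q3 tumour 3 gave 1, and leaving out q2 tumour 2 together with q3 tumour 1, a choice made after the data were seen, gave 37. The smallest adjusted p was 0.22, for Rec8, a meiotic cohesin gene (53.9 ± 55.6 CPM in q2 tumours, n = 3, and 0.583 ± 0.758 in q3 tumours, n = 4), and Adgre4, a receptor gene of myeloid cells (1.93 ± 0.218 and 0.121 ± 0.112 CPM). The next lower values in q3 tumours were those of Tspoap1 (15.6 ± 12.4 and 1.24 ± 0.905 CPM), Tnfaip3, which encodes the NF-kB feedback inhibitor A20 (34.3 ± 12.6 and 11.8 ± 2.58 CPM), and Fabp4 (57.6 ± 16.3 and 14 ± 6.5 CPM), and the adjusted p of each was 0.42. The 5 genes with the smallest unadjusted p among those higher in q3 tumours were Akr1c12 (0.789 ± 0.17 CPM in q2 and 36 ± 38.9 in q3 tumours), Colgalt2 (2.62 ± 1.63 and 12.3 ± 5.17), Adra2a (9.49 ± 4.32 and 46.5 ± 16.3), Gfra1, a receptor of a glial growth factor (3.75 ± 2.35 and 148 ± 153), and Zfpm2 (3.57 ± 2.37 and 24 ± 17), again at an adjusted p of 0.42.

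Within the lists chosen for this comparison no member passed over all genes, and the values were as follows. In the NF-kB target list, with a median log2 fold change of -0.55 and 2 of 33 members passing adjusted over the list alone, Cd83 was at 6.88 ± 1.66 CPM in q2 and 2.09 ± 0.595 in q3 tumours (-1.77 ± 0.39, adjusted p = 0.42), beside Tnfaip3 (-1.52 ± 0.29). In the NF-kB pathway list, with a median of -0.06 and 0 of 23 adjusted over the list alone, Traf6 was at 65.8 ± 6.17 and 98.2 ± 9.64 CPM and Tbk1 at 119 ± 42.3 and 72.2 ± 15.3 CPM. Neuroendocrine genes had a median of 0.26 with 0 of 28 adjusted over the list alone, and Snap25 was at 174 ± 14.2 and 474 ± 253 CPM and Cplx2 at 477 ± 218 and 859 ± 234 CPM, both of them genes of synaptic vesicle release. Among the subtype regulators, Foxa1 was at 128 ± 48.3 and 392 ± 220 CPM and Myc at 10 ± 3.39 and 4.68 ± 0.827 CPM. E2F target and mitotic genes had a median of -0.15 with 0 of 48 adjusted over the list alone. Cenpa was at 36.7 ± 10.5 and 19.8 ± 3.99 CPM and Rrm2 at 79 ± 44.9 and 41.4 ± 12.4 CPM. The p53 targets had a median of -0.49 with 0 of 25 adjusted over the list alone. T cell genes had the lowest median of the immune lists, -2.51, and 9 of 15 members passed adjusted over the list alone, all lower in q3 tumours, with Cd8a at 3.07 ± 3.17 and 0.0985 ± 0.0761 CPM and Cd28 at 5.23 ± 4.92 and 0.778 ± 0.389 CPM. By the same measure 8 of 14 B and plasma cell genes, 7 of 10 class II genes, 5 of 22 interferon response genes and 4 of 9 natural killer cell genes passed, as did 5 of 9 adipocyte genes (median -3.73) and 2 each of the macrophage, class I and liver lists. Apart from these lists and the NF-kB targets, every list had 0. T and B cell genes overlapped between the groups, at a median of 7.54%, 21.9% and 72.9% of their normal lung level in q2 tumours 1, 2 and 3. In q3 tumour 1 they were at 9.6%, and in the other q3 tumours at 2.38% to 4.16%. The lower level in q3 tumours thus leaned on q2 tumour 3 most. Adipocyte genes overlapped between the groups as well, at a median of 0%, 458% and 408% of their normal lung level in q2 tumours 1, 2 and 3. They were at 65% in q3 tumour 1 and at 0% to 6.79% in the other q3 tumours. In class I, H2-Q7 was at 15.2 ± 4.09 and 2.93 ± 1.66 CPM and Nlrc5 at 31.3 ± 15 and 7.86 ± 2.63 CPM. Of the other lists, Ccr2 (macrophage) was at 22.8 ± 21.1 and 5.04 ± 2.91 CPM, and Lcn2 (neutrophil) at 30.9 ± 35.9 and 123 ± 82.7 CPM. Cd177, a neutrophil gene, was at 42.1 ± 71.5 and 6.19 ± 5.68 CPM, a mean that rested on 125 CPM in q2 tumour 2. In the CREB pathway Pck1 was at 12.5 ± 11.2 and 0.48 ± 0.843 CPM and Prkar1b at 57.3 ± 8.4 and 126 ± 80.1 CPM. The sign of the median, the mean and camera's direction differed for the ciliated cell, fibroblast, smooth muscle and neutrophil lists. Camera called none of the 30 lists with an estimated correlation (adjusted p from 0.31 to 0.99), fry called 0 of them, and 16 passed with the preset correlation of 0.01. In simulated data of this size, where 200 genes changed, edgeR called 40 of 100 genes changed 4-fold and 3 of 100 changed 2-fold. If as few genes differ between these tumours, most differences of 2-fold would be missed. The q2 tumours differed among themselves in lymphocyte genes: Cd3e was at 0.312, 0.772 and 5.43 CPM in q2 tumours 1, 2 and 3.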

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

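The tests on neuroendocrine transcripts in normal lung and on lymphocyte transcripts in q2 tumour 3 were chosen after those results were seen, and the counts over other splits and the tests on separately counted libraries before. In the groups of 4 samples, each of 140 genes that the rule took was searched for a sample far from the others. The measure was the gap to the nearest sample as a share of the group's range in log2(CPM + 0.5), against Dixon's 95% critical value. Of 280 groups 17 exceeded it (6.1%), where chance gives about 5%, so the share lies close to that of chance. Groups of 3 were not tested.

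In 6 of the 17 the sample was q3 tumour 1, always as the highest. Its Mycl level was 145 CPM against 38.9 to 48.6 in the other q3 tumours (gap 0.832 of the range). The death receptor gene Fas was at 9.68 against 3.17 to 3.63 CPM (0.884), and Tcf21, a gene of lung fibroblasts, at 5.34 against 0.453 to 0.666 CPM (0.889). Near the detection floor, Cidec was at 1.24 CPM against 0.0605 or less (0.908), Cr2 at 0.993 against 0.0605 or less (0.896) and Vsnl1 at 1.24 against 0.0881 or less (0.87). In other q3 tumours, Iapp was at 16.7 CPM in sample 3 against 2.11 to 2.73 (0.888) and Cd28 at 1.36 in sample 2 against 0.528 to 0.62 (0.855).

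In normal lung, sample 1 had the lowest level of the mitotic kinase gene Cdk1, 5.37 CPM against 19.1 to 22.1 (0.892), and the highest of the ciliated cell gene Tppp3, 231 against 131 to 140 CPM (0.876). Sample 2 had the lowest Rb1, 130 against 156 to 161 CPM (0.869), and the lowest level of the Y-linked gene Kdm5d, 0.227 against 23.2 to 48.1 CPM (0.8295). Sample 3 had the highest Nfkb2, 87.7 against 35 to 39.3 CPM (0.876), and the highest Akr1c12, 2.24 against 0.908 to 0.968 CPM (0.937). It had the lowest Sfta2, 20 against 32.2 to 34.2 CPM (0.889), and the lowest Traf6, 68.4 against 76.4 to 77.6 CPM (0.873). Sample 4 had the lowest level of the pericyte gene Higd1b, 10 against 21.6 to 22.2 CPM (0.964).

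Normal lung samples 2, 3 and 4 held neuroendocrine transcripts that sample 1 had little of: Chga was at 3.22, 91, 43 and 75.8 CPM in samples 1 to 4 and Scg2 at 2.52, 48.6, 12.9 and 41.3 CPM. Reads spread evenly over silent genes are argued against, because the median level of 5083 genes silent elsewhere was at most 0.027 of the median rise of the neuroendocrine genes in these 3 samples. Samples 2 and 4 did carry such silent genes at a low level, a median of 0.454 and 0.645 CPM, against 0 in sample 3. Samples 2 and 4 were also the shallowest of normal lung, with 4640011 and 3200987 fragments against 21719193 and 18264800 in samples 1 and 3. The deeper library of sample 2 (3222785 fragments) still had 16113 genes at 5 or more fragments. The deeper library of sample 1 (15918423 fragments) had 15610. What brought these further genes into samples 2 and 4 was not tested. RNA of tumour cells in these samples remains a candidate explanation. In samples 2, 3 and 4, 272 other genes abundant in tumours and low in sample 1 stood at 10.58%, 3.89% and 9.59% of their tumour level. The 22 neuroendocrine genes stood at 7.87%, 2.69% and 7.36% (lowest ratio 1.3). Genes picked as abundant in tumours cannot show whether genes that tumours lack rose too. In samples 2 and 4 Mroh2a was at 19.3 and 26.5 CPM, against 0.264 or less in every tumour. Fga was at 24.3 and 15.5 CPM, against 5.59 or less. Tumour RNA does not account for Mroh2a and Fga, and other genes were not searched for this. Cell cycle genes stood at 12.57%, 11.27% and 12.69%, which in sample 3 is more than tumour cells at the neuroendocrine share would bring, so tumour cells alone do not account for them. No biological explanation was tested, and other cells that express the same genes stay open, since the 272 genes were picked by their low level in sample 1.

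When the libraries of a sample were counted as separate replicates, as in the design written beforehand, edgeR called 1489 genes between q3 and q2 tumours, in place of 0. If the male sample among the q2 tumours were the cause, most calls should be lost with the level of Y-linked genes as a covariate. With it 1613 genes were called. That covariate was fitted over normal lung too, and only 1 tumour sample was male, so the count cannot exclude the male sample. Counting 2 libraries of a sample as 2 replicates stays a likely cause: in 12 of the 35 splits of the 7 tumour samples, the real one included, as many genes were called, with a highest other split of 2950 and a median of 1004. The vector, which the design names, stays open and untested as a source of some of these genes, since it is not known which group carries which vector.

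In q2 tumour 3, T and B cell genes stood at a median of 72.9% of their normal lung level, against 7.54% and 21.9% in q2 tumours 1 and 2 and 2.38% to 9.6% in the q3 tumours. Lung tissue left in the tumour piece is argued against, because alveolar genes were at 2.13% of their normal lung level there, a ratio of 0.029 to the lymphocyte genes. Lymphoid tissue beside the tumour, or lymphocytes within it, may be the source, and neither was tested. Adipocyte genes were at 408% of their normal lung level in this sample and at 458% in q2 tumour 2, at 65% in q3 tumour 1 and at 0% to 6.79% in the other tumours. Ms4a1 stood at 20.1 CPM and Cd3e at 5.43 CPM there.

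Each comparison was set against all splits of the same samples into groups of the same sizes. For q2 tumours against normal lung 1 of 35 splits, the real one, gave as many genes (5781, highest other 4). For q3 tumours against normal lung it was also 1 of 35 (7389, highest other 1), the smallest share that 35 splits can give. Every other split puts tumours and normal lung in the same group, so low counts there follow from the tissue difference. The splits show that the counts go with the division of tumour from normal lung, and cannot exclude chance. With normal lung samples 2 and 4 left out, a choice made after the data were seen, 4267 and 5714 genes were called. For q3 against q2 tumours the real count is 0, which all 35 of 35 splits must reach (highest other 81), so the splits decide nothing there. EdgeR had 1600 genes at an unadjusted p under 0.05 there, and DESeq2, which called 38 unchanged genes in simulated data, called 113.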

How the results depend on the processing

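The fit of separately counted libraries was the design written beforehand, and was replaced once the pairs were seen. Chosen after the data were seen were the deeper library of each pair and the removal of genes that differ between libraries. So were the removal of normal lung samples 2 and 4 and that of q2 tumour 2 with q3 tumour 1. Single-sample removal for the lists and for q3 tumours against normal lung was also chosen then. Of the gene counts over alternatives 65 stayed within 1.5 times the reported count. For q2 tumours against normal lung (5781) the exceptions were 9095 with all 20 libraries counted separately and 3411 at an adjusted p under 0.01. For q3 tumours against normal lung (7389) they were 3925 with the sex covariate, where the q3 tumours are all female, and 4877 at an adjusted p under 0.01. For q3 against q2 tumours (0) they were 113 by DESeq2, 2 by limma on log2(FPKM + 0.1), 2 with 1 surrogate variable, 1489 with 20 libraries and 37 without q2 tumour 2 and q3 tumour 1. Without single samples they were 0 to 7, with 7 without q2 tumour 2 and 1 without q3 tumour 3. Without single samples 4322 to 5636 genes were called for q2 and 6193 to 7494 for q3 tumours against normal lung. A stricter threshold gives fewer genes by construction, and the cause was not tested for the others. With library size alone the median log2 fold change was 0.29 (q2 tumours against normal lung), 0.12 (q3) and -0.15 (q3 against q2 tumours), in place of 0, -0.03 and -0.01, and most called genes were then higher: 4075 of 6469 for q2 and 4115 of 7558 for q3 tumours, against 2754 of 5781 and 3496 of 7389.

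Camera's 0 lists became 21, 23 and 16 with a preset correlation, fry gave 22, 26 and 0, and 20 libraries gave 1 list for q3 tumours against normal lung, where single-sample removal gave 0 to 1 (1 without normal lung sample 3). Trp53 in q2 tumours lost its call with library size alone (-0.89), no filter (-1.08), the sex covariate (-1.02) and without normal lung samples 2 and 4 (-1.18), and was -1.30 to -0.95 without single samples. In q3 tumours Trp53 lost it with the sex covariate (-1.0) and without normal lung samples 2 and 4 (-1.21), and Mycl with the sex covariate (1.82). Rb1 and Nfkbia kept their calls against normal lung in all alternatives. Between q3 and q2 tumours, where no value passed, signs turned for Trp53 (0.05 by limma-voom, 0.02 with the sex covariate, -0.25 to 0.09 without single samples), Mycl (-0.87 to 0.01), Nfkbia (-0.05 with library size alone, -0.12 to 0.25 without single samples) and Cd177 (0.61 by limma-voom, 2.09 without q2 tumour 2 and q3 tumour 1, -3.55 to 2.91 without single samples). The cause was not tested, but Cd177 rests on q2 tumour 2. Of the values of other named genes over alternatives 3528 kept direction and side of the threshold, 190 no longer passed, 47 newly passed and 3 turned. Among the alternatives that leave out no single sample, most named calls ended with the sex covariate (11 for q2 and 21 for q3 tumours against normal lung), without normal lung samples 2 and 4 (13 and 10) and by limma-voom (7 and 6), and the others ended 6 or fewer each. The shallowest sample limits genes at a few CPM, and 2-fold changes were mostly missed in simulated data where 200 genes changed.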

Other observations

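The genes and samples below were chosen after their values were seen, so they are given per sample and not tested. Tumours of the q3 group differed among themselves in neuroendocrine and neuronal transcripts. Neurod1, a neuronal transcription factor, was at 165 and 127 CPM in q3 tumours 2 and 4, and at 14.5 and 0.121 CPM in q3 tumours 1 and 3. Chgb, a granin gene, was at 1940 and 1840 CPM in samples 2 and 4 against 277 and 380 CPM in samples 1 and 3. Another granin gene, Scg2, went the other way, with 57 and 73.6 CPM against 657 and 1380 CPM. The transthyretin gene Ttr was at 203 and 201 CPM in samples 2 and 4 and at 30.8 and 17.9 CPM in samples 1 and 3. Ahsg was at 38.9 and 58.9 CPM against 0.62 and 1.15 CPM, and the apolipoprotein gene Apob at 24 and 26.3 CPM against 0.745 and 0.363 CPM. Among the q2 tumours, Neurod1 was at 26.2, 13.3 and 66.9 CPM in samples 1, 2 and 3.

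The tumours also held different amounts of transcripts of other tissues. The surfactant gene Sftpc was at 915 CPM in q2 tumour 2 and 1080 CPM in q3 tumour 1, against 1.95 to 278 CPM in the other tumours and 2880 to 7780 CPM in normal lung. Adipoq, a hormone gene of fat cells, was at 9.01 and 7.49 CPM in q2 tumours 2 and 3, and at 1.24 CPM or less in the other tumours. The muscle gene Myl4 was at 68 CPM in q2 tumour 2 and at 124 CPM in normal lung sample 1. Normal lung sample 4 held both Xist (548 CPM) and the Y-linked gene Ddx3y (88.4 CPM). In the other normal lung samples Xist was at 14.5 and 39.1 CPM where Ddx3y was at 187 and 201 CPM, and at 2440 CPM where Ddx3y was at 0. What gave both kinds of transcript in sample 4 was not tested.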
